A study of Drosophila melanogaster with 55 samples.

How the data were processed

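The series profiled early Drosophila melanogaster embryos by RNA sequencing and by chromatin immunoprecipitation with sequencing (ChIP-seq). Of its 55 samples, 41 came with a file: 12 tables of RNA counts and 29 lists of ChIP-seq peaks. The other 14 samples were input DNA without a file of their own. Input entered only through the authors' peak calls, which for the knockdown and F578A lists were made against input, per the file headers.

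The RNA tables held raw counts per repeat name as the authors deposited them, and featureCounts 1.6.5 is the counting tool named, per the submitters' processing notes. All copies under a repeat name were counted together, and the tables held 9263 names and no genes. A simple repeat could stand under several names, 1 for each rotation or strand of its motif. A value for such a name covers that name alone. Of these names, 9028 were simple repeats, 6 low-complexity repeats, 4 ribosomal RNA, 208 transposable elements and 17 other repeats. How reads that map to several places were counted, whether strand was used, and which repeat annotation was used were not given in the sources used here, so related elements with shared sequence could have exchanged reads. Total RNA came from single embryos, per the labels' protocols. Because no gene was counted, the level of Gcn5, of w (white) or of SetDB1 could not be checked in any sample.

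The peak lists of the knockdown and F578A experiments, 20 in number, came from MACS 2.2.6 in broad mode with a broad cutoff of 0.1, against input and after removal of duplicates, per the file headers. Input depth was the same for all antibodies of a replicate, so these lists shared an input. Trim Galore 0.6.0, Bowtie2 2.3.5.1 and deepTools are named as further tools, without their roles, per the submitters' processing notes. The same notes name the builds dm6 and BDGP6, and the peak coordinates fit the chromosome lengths of dm6. These lists give for each peak the fold enrichment over input and the −log10 p-value and −log10 q-value that the authors deposited, with the signal as a pileup of coverage, per the file headers. The 9 lists of the w1118 stage series had no settings in a header. Those for H3K14ac had the columns of a broad list, and those for H3K9me2 and H3K9me3 had the 10 columns of a narrow list with summits, including a score and a signal that the authors deposited. Their control, threshold and depth were not given in the sources used here, so broad and narrow lists were not compared in length. Fold enrichment and −log10 q as deposited by the authors were used to rank or filter peaks within a list. Averaged over the libraries of a group, fold enrichment was also used to rank, describe and stratify regions. Depth was taken as fragments after filtering, per the file headers.

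Counts were compared with edgeR 4.0.16 in R 4.3.3, with limma 3.58.1 for lists of repeats. Libraries were scaled by TMM, repeats were kept by filterByExpr, and groups were compared by the quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05. Scaled counts (CPM, reads of a repeat relative to the library size) were computed from the deposited counts with the TMM library sizes of each comparison. The Gcn5 knockdown was compared with the knockdown of w, and SetDB1 F578A with SetDB1 WT, with 3 libraries per group. The difference between both effects was tested as an interaction in all 12 libraries. Lists of repeats were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. The lists were the LTR elements with the Gypsy, Copia and Pao families, the LINE elements with the Jockey group, the R1, R2 and I group and the telomere elements, the DNA elements with the P group and the Tc1-mariner group, FB and NOF, Helitron and INE-1, satellites, simple repeats, low-complexity repeats, rRNA, and simple satellites of heterochromatin and of the Y chromosome. The P group pooled P and PROTOP elements with HOBO, Transib elements and LOOPER1_DM. Lists with fewer than 3 tested members received no list test. The family of list tests held 16 lists per comparison.

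Same-numbered replicates of the Gcn5 and w knockdowns deviated together from their group means, with correlations across repeats of 0.61, 0.26 and 0.46, so the numbers were treated as pairing the samples, although the labels do not say what a number stands for. The fit without the pairing stayed the primary one, and results with the replicate number as a block stand beside it where they differ. The pairing was thus inferred from the same counts that the blocked fit then tested. Differently numbered libraries of the Gcn5 and w knockdowns correlated at 0.14 at most. In the F578A experiment the same-numbered correlations were 0.69, -0.11 and -0.04, and the numbers were not treated as pairs. There F578A replicate 3 and WT replicate 2 correlated at 0.73, so a high correlation alone does not show a pairing. Replicates within a group differed far beyond counting error, with a chi-square per degree of freedom between 10.0 and 99.1 for pairs of libraries. What a replicate was biologically is not stated beyond its number, so p-values across replicates may measure technical spread only.

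The counting script was tested on simulated counts with 200 changed repeats. The changed repeats had a mean of at least 20 counts, and all repeats were drawn independently of each other. In the design of the Gcn5 comparison (2065 repeats tested) it recovered 84.0% of repeats changed 4-fold and 31.0% of those changed 2-fold, and with the replicate block (2062 repeats tested) 91.9% and 51.0%. In the design of the F578A comparison (2282 repeats tested) it recovered 86.7% and 34.0%. Without the block, 6 of 121 calls were false in the Gcn5 design and 8 of 127 in the F578A design. Far fewer repeats passed in the data, where repeats also moved together within groups, so recovery there may be lower. The interval script was tested on 20 simulated sets, and every overlap was right in 20 of them.

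Peaks were assigned to compartments of dm6: centromere-proximal heterochromatin (2L from 22 Mb, 2R to 5.4 Mb, 3L from 23 Mb, 3R to 4.2 Mb, X from 22 Mb), chromosome 4, the Y chromosome, and the arms. The heterochromatin share is the covered length in proximal heterochromatin, chromosome 4 and Y over that length plus the arms, with unplaced scaffolds and the mitochondrial genome left out. For each library the number of peaks, the covered length and this share were computed and compared by an exact two-sided permutation test. With 2 libraries against 2, this test cannot give a p below 0.333, so differences are given as values with the libraries side by side. Control regions were the overlaps of peaks found in both control libraries. A control region was kept if both treated libraries had a peak on it (an overlap of 1 bp) and lost if neither had. Shares of regions carry 95% Wilson intervals, which cover counting error only. Overlaps between peak sets were set against 1000 circular shifts of the peak midpoints within each compartment, without unplaced scaffolds. Assembly gaps and unmappable sequence were not masked, so shifted peaks could land where no peak can be called. Gene names came from the annotation of the same build.

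Comparisons, tests, lists, compartments, the rule for named repeats and regions, and most alternatives were fixed before the data were examined. The rule named, per comparison, up to 8 repeats per direction that passed the threshold with a mean of at least 20 counts and groups that did not overlap. Where fewer than 5 passed, it named the 5 with the smallest p. It also named a fixed set of transposable elements and satellites whatever their p, and the 5 strongest regions of each kind per ChIP-seq comparison. The alternatives were DESeq2 1.42.0 size factors and its Wald test, scaling by total counts, no filter on low counts, a mean of at least 50 counts, transposable elements alone, the replicate block, all 12 libraries in one fit, and each library left out. For peaks they were a −log10 q of at least 5, a fold enrichment of at least 2, merging of peaks closer than 1000 bp, borders moved by 1 Mb, the same number of peaks per library, an overlap of at least 50%, and each library left out. Fits of transposable elements alone with the block or with DESeq2 were added after the data were seen. Figures and interval counts were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.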

Results

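The RNA libraries came from single embryos at stage 5, when the blastoderm becomes cellular and the zygotic genome is being switched on. There were 3 libraries each of embryos with a germline knockdown of Gcn5, of embryos with a knockdown of w (white, an eye colour gene that serves as the control), of SetDB1 F578A embryos and of SetDB1 WT embryos. Gcn5 is a histone acetyltransferase. SetDB1, called Eggless in flies, is a methyltransferase that places methyl groups on lysine 9 of histone H3 (H3K9), the mark of constitutive heterochromatin. F578A replaces a phenylalanine of SetDB1 with alanine. ChIP-seq measured GFP-tagged SetDB1, H3K14ac (acetylation of histone H3 on lysine 14) and H3K9me3 in both knockdowns, and GFP-SetDB1 and H3K9me3 in F578A and WT embryos, with 2 libraries per group. A series of w1118 embryos, a standard white-eyed strain, at stages 4, 5 and 6 gave 1 library each for H3K14ac, H3K9me2 and H3K9me3.

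RNA libraries held between 1.92 and 3.21 M counts on repeats. Most counts fell on simple repeats, from 77.6% to 85.8% of a library. Transposable elements took 2.67% ± 0.0745 (SD, n = 3) in the Gcn5 knockdown, 2.92% ± 0.29 in the w knockdown, 4.96% ± 0.979 in F578A and 3.99% ± 0.677 in WT. Ribosomal RNA took between 0.814% and 9.16%.

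The series title names a recruitment of SetDB1 through H3K14ac, and the knockdown of Gcn5 asks what happens to transposable elements and chromatin when a writer of histone acetylation is reduced in the early embryo. A pair of transposons differed between the Gcn5 and w knockdowns, in opposite directions. Mariner2_DM, a DNA transposon of the mariner family that moves by excision, rose in the Gcn5 knockdown. DM412, a retrotransposon of the Gypsy family that moves through an RNA copy, fell. Among 2142 repeats tested, edgeR's quasi-likelihood test called 1 up and 1 down.

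Mariner2_DM stood at 210, 249 and 302 CPM in the Gcn5 knockdown and at 16.5, 23.1 and 16.5 CPM in the w knockdown, a log2 fold change of 3.76 (SE 0.358, edgeR adjusted p = 0.00022). DM412 stood at 79.2, 91.7 and 207 CPM against 814, 603 and 535 CPM, a log2 fold change of -2.37 (SE 0.386, adjusted p = 0.038). The call of DM412 rested on several libraries: without replicate 2 of the Gcn5 knockdown, or without replicate 2 or 3 of the w knockdown, it no longer passed, and its adjusted p ranged from 1.2e-14 to 0.483 over 16 alternatives. Mariner2_DM passed in all 16, with adjusted p between 2.7e-31 and 0.0056. The rule of the 5 smallest p also named 3 repeats that did not pass with edgeR: the LTR retrotransposon end BURDOCK_LTR (log2 fold change 3.94, SE 0.773, adjusted p = 0.111, 32.1, 41.5 and 32.4 CPM against 2.82, 0 and 3.71), and the simple repeats (AGATGG)n (-4.11, adjusted p = 0.111) and (TTACGTT)n (-2.30, adjusted p = 0.147). With DESeq2 all 3 passed, with adjusted p of 4.1e-06, 5.8e-05 and 0.00051, and over all alternatives they reached up to 0.654, 0.654 and 0.73 (lowest 1.3e-15, 1e-06 and 5.8e-07).

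When same-numbered libraries of the Gcn5 and w knockdowns were paired by a replicate block, many more repeats passed. The pairing itself was inferred from these counts. The blocked fit called 28 up and 45 down, of which 8 up and 8 down were transposable elements and 20 up and 36 down simple repeats. BURDOCK_LTR then had an adjusted p of 5.8e-07. POGO, a DNA transposon of the Tc1-mariner group, rose by a log2 fold change of 1.26 with an edgeR adjusted p of 0.00012 with the block and 0.15 without. DM412B_LTR, the terminal repeat of a relative of DM412, moved against it, with a log2 fold change of 1.37 with the block (adjusted p = 9e-05) and 1.43 without (0.177). The internal part of the Gypsy element MDG3_I-int fell by 1.42 with the block (adjusted p = 0.0017, and 0.339 without). POGO, DM412B_LTR and MDG3_I-int were chosen after their values were seen.

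The telomere of Drosophila is built from the retrotransposons HETA, TART and TAHRE in place of a telomerase repeat. HETA stood at 103, 148 and 158 CPM in the Gcn5 knockdown and at 94.0, 61.0 and 44.5 CPM in the control (log2 fold change 1.04, SE 0.374, edgeR adjusted p = 0.627 and 0.036 with the block). TART_B1, chosen after its values were seen, fell by 1.12 with the block (adjusted p = 0.012, and 0.538 without). TART had a log2 fold change of -0.43 and TAHRE of 0.46, with adjusted p of 0.398 and 0.693 with the block. The retrotransposon Copia_I-int had a log2 fold change of -1.0 (edgeR adjusted p = 0.484 and 0.019 with the block), and DOC, a LINE of the Jockey group, 1.13 (0.712 and 0.061). Other elements on the fixed list had log2 fold changes of -0.57 (the Gypsy element DM297_I-int), 0.05 (ROO_I-int), 0.39 (R1_DM) and 0.58 (R2_DM), the last pair being LINEs that insert into ribosomal RNA genes, and of 0.21 (FW_DM), -0.31 (LINEJ1_DM) and 0.33 (HOBO). DNAREP1_DM, the abundant INE-1 element, had -0.09, PROTOP_B -0.14, and the satellites SAR_DM and (AATAT)n 0.07 and 0.28. The name (AAGAG)n, and the satellite represented here by (AACATAGAAT)n, had too few counts to test in either comparison. The satellites of (AATAT)n and (AAGAG)n also stood under other names, such as (ATATA)n and (AGAGA)n.

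Groups did not overlap for 222 of the 2142 repeats, where chance gives 10% for 3 libraries against 3 without pairing. 119 repeats had an unadjusted p under 0.05. Among transposable elements fitted alone, edgeR called 4 up and 4 down, and DESeq2 called 9 up and 5 down among all repeats. Without replicate 1 of the Gcn5 knockdown edgeR called 13 repeats, and without replicate 1 of the w knockdown 8.

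**Figure D1:**
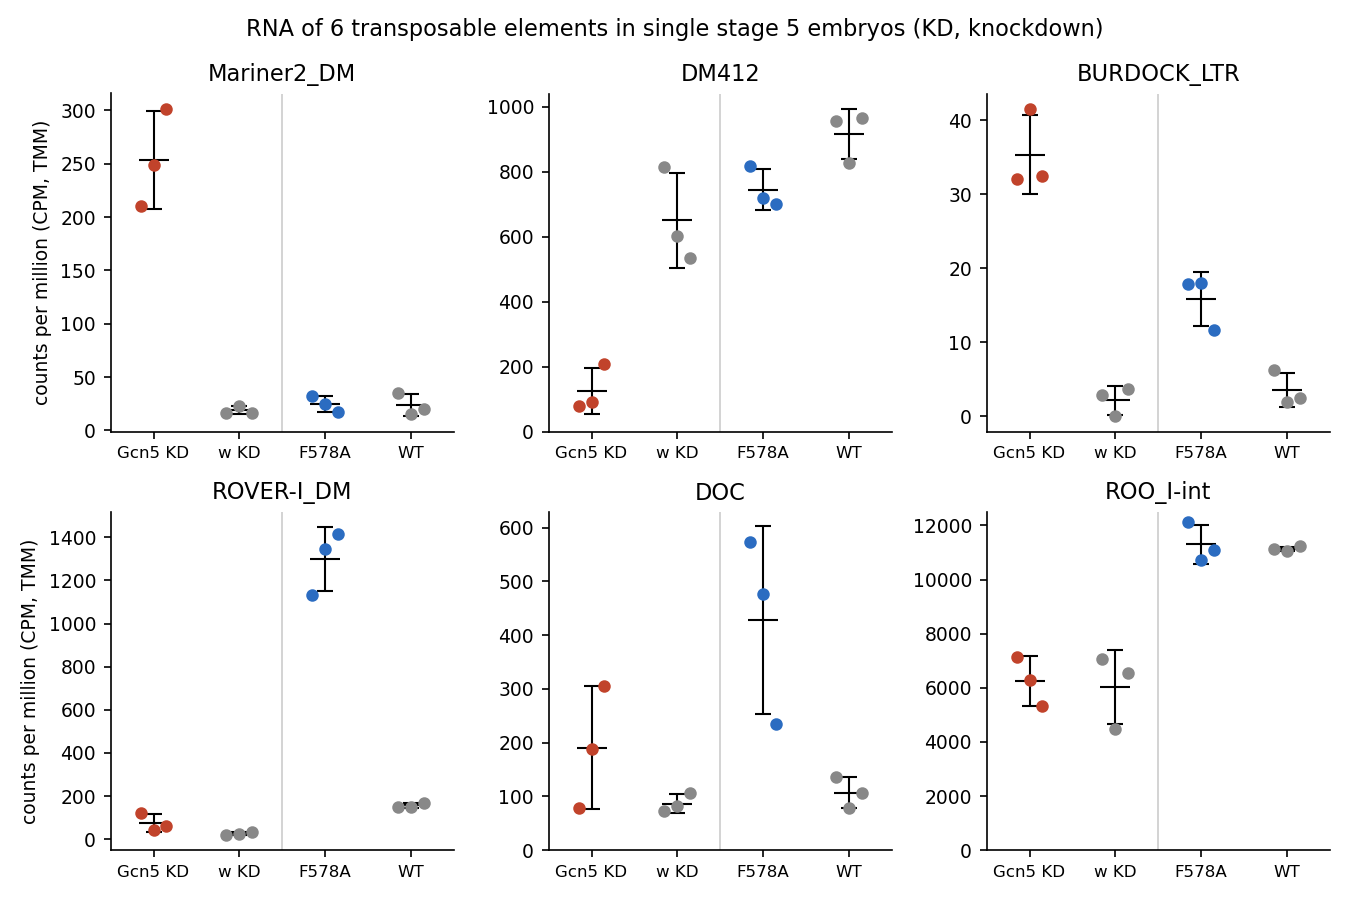
Scaled counts (CPM) of 6 transposable elements in each RNA library, with mean and SD of 3 libraries per group. Mariner2_DM averaged 253 CPM in the Gcn5 knockdown and 18.7 in the w knockdown, and ROVER-I_DM 1298 CPM in F578A and 157 in WT.

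In the Gcn5 knockdown no list of repeats passed the camera test at the preset correlation with all libraries. Without replicate 1 of the Gcn5 knockdown 3 lists passed, without its replicate 2 there were 2, and without its replicate 3 or replicate 1 of the w knockdown 1. With an estimated correlation and all libraries every list had an adjusted p of 0.959. Of 104 LTR elements tested, 53 had a positive log2 fold change (median 0.04, camera adjusted p = 0.882). Adjusted over the list alone, 4 of them were up and 2 down, against 0 up and 1 down adjusted over all repeats. In the Gypsy family the split was 42 of 74 (median 0.15, adjusted p = 0.745, 4 up and 3 down over the list alone), and in the Pao family 7 of 15 (median -0.05, mean 0.11, test direction down, adjusted p = 0.882). All 7 Copia elements tested had a negative log2 fold change (median -0.36), with a camera adjusted p of 0.355, and of 0.053 with the replicate block.

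Among LINE elements, 20 of 38 were positive (median 0.03, adjusted p = 0.8). In the Jockey group 11 of 24 were positive (median -0.06, mean -0.01, test direction up, adjusted p = 0.882), in the R1, R2 and I group 7 of 9 (median 0.21, adjusted p = 0.61) and among telomere elements 2 of 4 (median 0.01, mean -0.04, test direction down, adjusted p = 0.882, 1 up and 1 down over the list alone). DNA elements had a median of 0.06 (15 of 25 positive, adjusted p = 0.777), the P group 0.26 (9 of 12, 0.777) and the Tc1-mariner group -0.08 (5 of 10, mean 0.13, adjusted p = 0.8), where Mariner2_DM and POGO were up and 1 element down over the list alone. Satellites had a median of 0.11 (adjusted p = 0.777), simple repeats 0.01 with a mean of -0.05 (0.8), low-complexity repeats 0.04 with a mean of -0.55 (0.61), and the simple satellites of heterochromatin and of the Y chromosome 0.11 and 0.09 (0.61 each). FB and NOF (median 0.07), Helitron and INE-1 (-0.09) and rRNA (0.05) had too few tested members for a list test.

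In SetDB1 F578A embryos one retrotransposon stood out. ROVER-I_DM, the internal part of a Gypsy retrotransposon, rose from 157 ± 11.5 CPM in WT to 1298 ± 148 CPM in F578A (mean ± SD, n = 3). Its 3 mutant libraries held 1132, 1346 and 1417 CPM against 152, 148 and 170 CPM. The log2 fold change was 3.05 (SE 0.138, edgeR adjusted p = 7.8e-05), and it passed under all 16 alternatives, with adjusted p up to 0.003. Among 2395 repeats tested, edgeR's quasi-likelihood test called 1 up and 0 down. 129 repeats had an unadjusted p under 0.05, and DESeq2 called 19 up and 10 down. Per the labels, the F578A embryos sequenced for RNA carried the CyO balancer chromosome and the WT embryos did not, so the mutation and the balancer cannot be told apart in this comparison.

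Several LTR elements and a LINE had large values without passing with edgeR. DOC, the Jockey LINE, stood at 574, 476 and 235 CPM in F578A and at 136, 77.9 and 106 CPM in WT (log2 fold change 2.01, SE 0.356, edgeR adjusted p = 0.151 and DESeq2 adjusted p = 3.9e-05, 1.6e-13 to 0.999 over 16 alternatives). ZAM_I-int, a Gypsy retrotransposon, had a log2 fold change of 2.01 (adjusted p = 0.136), BURDOCK_LTR of 2.17 (0.36), BLOOD_LTR of 1.81 (0.463) and FROGGER_I-int of 1.35 (0.36). In the fit of transposable elements alone these 5, with ROVER-I_DM, ZAM_LTR and Gypsy12_LTR, were the 8 called up, and DMLTR5 and POGON1 the 2 called down. These elements except DOC and ROVER-I_DM were chosen after their values were seen. The simple repeats with the smallest p were (ATCTAC)n (log2 fold change 2.69, adjusted p = 0.111), (CCGGCT)n (-0.95), (GCCCTC)n (-2.70) and (GTGTACT)n (-2.64), the last 3 with an edgeR adjusted p of 0.136. (GTGTACT)n stood at 14.9, 15.4 and 40.7 CPM in F578A and at 117, 156 and 169 CPM in WT. All 4 passed with DESeq2, with adjusted p of 7e-08, 2.1e-05, 9.5e-05 and 2.4e-06 in the same order. Over the alternatives that of (GTGTACT)n ranged from 2.7e-12 to 0.99, and the other 3 had their lowest with DESeq2 and reached up to 0.971, 0.99 and 0.99.

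Both elements that passed in the Gcn5 knockdown showed little difference here: Mariner2_DM had a log2 fold change of 0.09 (adjusted p = 0.981) and DM412 of -0.30 (0.899). HOBO, a DNA transposon, had 0.72 (adjusted p = 0.281) and the satellite name (AATAT)n 0.90 (0.426). With DESeq2 both passed (0.0162 and 0.044, over all alternatives 0.0135 to 0.999 and 0.044 to 1). Other fixed elements had 0.84 (Copia_I-int), 0.66 (DM297_I-int), 0.59 (FW_DM), 0.52 (HETA), 0.50 (TAHRE), 0.44 (LINEJ1_DM), 0.42 (SAR_DM), 0.35 (R1_DM), 0.28 (PROTOP_B), 0.25 (DNAREP1_DM), 0.02 (ROO_I-int), -0.03 (R2_DM) and -0.21 (TART), with adjusted p from 0.899 to 0.981. Groups did not overlap for 295 of the 2395 repeats, where chance gives 10%. Without replicate 3 of F578A, 3 repeats were called.

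In F578A, LTR and LINE elements ranked above the other repeats in the camera test at the preset correlation, and no such call held with an estimated one. Of 114 LTR elements 89 were positive (median log2 fold change 0.30, camera adjusted p = 3.4e-09, adjusted p = 0.557 with an estimated correlation). The Gypsy family (63 of 81, median 0.29, 6.9e-08), the Copia family (8 of 8, median 0.72, 0.00068) and the Pao family (11 of 16, median 0.36, 0.0052) each had an adjusted p = 0.557 with an estimated correlation. So did the LINE elements (31 of 38, median 0.22, 0.00089), the Jockey group (20 of 24, median 0.26, 0.001) and the P group of DNA elements (10 of 12, median 0.34, 0.0063), while DNA elements (20 of 25, median 0.23, 0.012) had an adjusted p = 0.59 with an estimated correlation. The P group holds HOBO, Transib elements and LOOPER1_DM beside the P and PROTOP elements, so its call is not one of P elements alone. Simple repeats were called down relative to the rest (adjusted p = 4.8e-09, adjusted p = 0.017 with an estimated correlation), although their median was 0.00 and their mean 0.04. The fry test called no list (lowest adjusted p 0.518). Transposable elements took 5.92%, 5.0% and 3.97% of the counts in F578A and 4.66%, 3.31% and 4.01% in WT, so the groups overlapped. Most of them also moved together along the main axis within groups, which held 83.9% of that variance. Without replicate 2 of WT, 3 lists passed in place of 9.

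Over each list alone, edgeR called 3 LTR elements up, all 3 of the Gypsy family, 1 Pao element, 1 Jockey element and 1 element of the P group, against 1 LTR element adjusted over all repeats. The R1, R2 and I group (median 0.11, camera adjusted p = 0.145), telomere elements (0.17, 0.495), the Tc1-mariner group (0.23, 0.174), satellites (0.32, 0.093), low-complexity repeats (-0.14, 0.068) and the simple satellites of heterochromatin (0.10, 0.302) and of the Y chromosome (0.10, 0.495) did not pass. FB and NOF (0.18), Helitron and INE-1 (0.25) and rRNA (-0.50) had too few members for a list test.

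In the fit without a block, the effects of the Gcn5 knockdown and of F578A differed for 1 element, Mariner2_DM. The difference in log2 fold change was 3.69 (SE 0.516, edgeR adjusted p = 0.0054) among 2458 repeats tested in all 12 libraries. DM412 had a difference of -2.10 (adjusted p = 0.125), ROVER-I_DM of -1.48 (0.619), BURDOCK_LTR of 1.78 (0.997) and DOC of -0.89 (0.997). 134 repeats had an unadjusted p under 0.05, and DESeq2 called 3 up and 3 down. With the replicate block edgeR called 4 repeats, and 13 with the block among transposable elements fitted alone. Scaling by total counts shifted the median difference from -0.01 to -0.19. Without replicate 1 or 3 of the Gcn5 knockdown, or without replicate 3 of F578A, 2 repeats were called. Across 2071 repeats tested in both, the log2 fold changes had a correlation of 0.069 (rank correlation -0.015), and across 166 transposable elements of 0.371 (0.22).

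**Figure D2:**
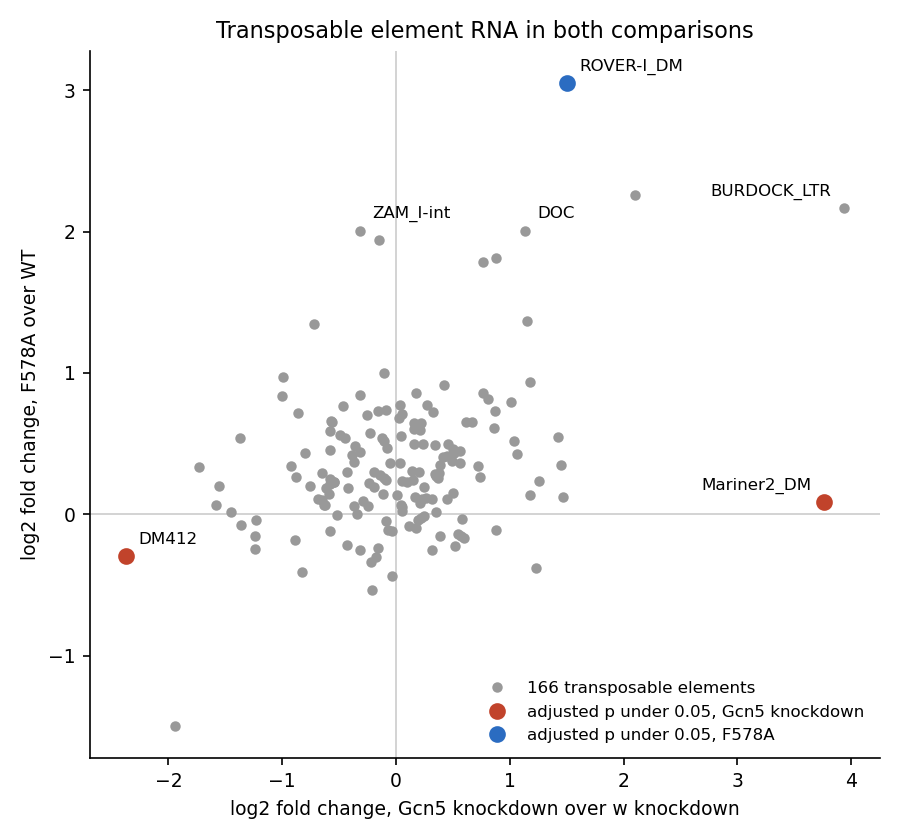
Log2 fold changes of 166 transposable elements in the Gcn5 knockdown and in F578A (correlation 0.371). Mariner2_DM lay at 3.76 and 0.09, DM412 at -2.37 and -0.30, and ROVER-I_DM at 1.5 and 3.05.

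On chromatin, GFP-SetDB1 had far fewer peaks in the Gcn5 knockdown. The knockdown libraries held 115 and 149 peaks, the w knockdown libraries 963 and 1409, a log2 ratio of -3.17, and the covered length was 0.091 and 0.126 Mb against 0.813 and 1.26 Mb (log2 ratio -3.26). With a −log10 q of at least 5 the log2 ratios were smaller, at -2.11 for number and -2.31 for length. The knockdown libraries were also shallower, with 1.63 and 2.08 M fragments after filtering against 5.37 and 6.05 M or 32.5% of the control depth. The exact permutation test gave p = 0.333, the smallest it can give, for number, length and share alike. The heterochromatin share was 40.6% and 35.5% in the knockdown and 52.1% and 46.9% in the control, a difference of -11.4 percentage points that turned to 6.83 with the same number of peaks per library, where the groups overlapped (40.6% and 36.7% against 17.4% and 46.2%).

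Of 627 regions with GFP-SetDB1 in both control libraries, 13.1% (95% Wilson interval 10.7 to 15.9) had a peak in both knockdown libraries and 77.0% (73.6 to 80.2) in neither. In heterochromatin, 5 of 191 regions were kept, and in the arms 12 of 152. Most of the 82 kept regions thus lay outside both, on unplaced scaffolds or the mitochondrial genome. With an overlap of at least 50% of the region 6.7% of all were kept, 2 in heterochromatin and 2 in the arms. Of the peaks in control replicates 1 and 2, 64.3% and 43.3% were found in the other replicate. Among the 5 strongest regions present in the control alone, 1 lay on an unplaced scaffold, 1 in Marf1, which encodes a meiosis regulator (2L:22338906-22339138, fold enrichment 2.92), 1 in Pzl, a gene for a Piezo-like channel (3R:2958816-2959091, 2.64), 1 at 1553 bp from Atf6 (2R:5142951-5143180, 2.55), and 1 in the Polycomb gene ph-p (X:2132281-2132443, 2.54). The single region found in the knockdown alone lay at 2L:21455194-21455575, 278 bp from the histone gene His3:CG33815.

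H3K14ac peaks were also scarcer in the Gcn5 knockdown. The knockdown libraries held 86 and 510 peaks and the control libraries 2158 and 832 (log2 ratio -2.33), over 0.044 and 0.337 Mb against 1.56 and 0.532 Mb (log2 ratio -2.46). Depth was 1.47 and 1.87 M fragments against 5.34 and 3.14 M, 39.3% of the control. The groups did not overlap (exact permutation p = 0.333). The heterochromatin share was 7.9% and 27.3% in the knockdown and 6.46% and 6.91% in the control, a difference of 10.9 percentage points. It was 1.61 with the same number of peaks per library, where the groups overlapped (7.9% and 13.8% against 9.38% and 9.12%), and 56.6 with a −log10 q of at least 5, where the knockdown libraries held only 5 and 24 peaks.

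Of 649 control regions with H3K14ac, 3.7% (2.5 to 5.44) were kept and 80.3% (77.0 to 83.2) lost. Replicates differed among themselves, since 29.4% of the peaks of control replicate 1 were found in replicate 2, and 77.5% the other way. The 5 strongest regions present in the control alone overlapped CG11018 (2R:19662512-19663455, fold enrichment 4.16), kel, a gene for the ring canals of the egg chamber (2L:18137566-18137889, 4.06), tho2, a gene of the THO complex of mRNA export (2L:2144864-2145162, 4.01), CG10492 (2L:19054176-19054690, 3.75) and His3.3A, a gene for the histone variant H3.3 (2L:5055261-5055532, 3.67). Only 4 regions were found in the knockdown alone, among them 1 at 5822 bp from Obp56g (2R:19777442-19777662) and 1 in Pzl (3R:3053836-3054082).

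H3K9me3 went the other way from both. Its peaks numbered 4899 and 5206 in the Gcn5 knockdown and 4138 and 3984 in the control (log2 ratio 0.32), and covered 10 and 11.7 Mb against 8.25 and 8.02 Mb (log2 ratio 0.42, exact permutation p = 0.333), at 76.7% of the control depth. On chromosome 4, a small chromosome rich in heterochromatin, H3K9me3 covered 6.62% and 7.2% against 3.36% and 3.44%. The heterochromatin share was 80.5% and 77.7% against 79.9% and 79.1% (difference -0.388 percentage points, overlapping groups, exact permutation p = 1). With peaks of a −log10 q of at least 5 the number and length were lower in the knockdown, with log2 ratios of -0.48 and -0.27. With a fold enrichment of at least 2 both were higher, with log2 ratios of 0.33 and 0.42.

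Of 3592 control regions with H3K9me3, 81.9% (80.6 to 83.1) were kept and 8.91% (8.02 to 9.88) lost. In heterochromatin 92.6% of 1845 regions were kept, and in the arms 68.8% of 741. Another 1120 regions were found in both knockdown libraries and in neither control library, 707 of them in heterochromatin and 334 in the arms. The strongest of these outside scaffolds lay at 2R:6382663-6382884 (fold enrichment 4.08), at X:11318504-11318736, 2843 bp from sisA, an X-linked signal of sex determination (3.77), and in Parp1 (3R:3558466-3560468, 3.70), the gene for poly(ADP-ribose) polymerase. The strongest region of the control alone outside scaffolds lay at 3L:23109920-23111544, 6460 bp from CkIIalpha (4.64).

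**Figure D3:**
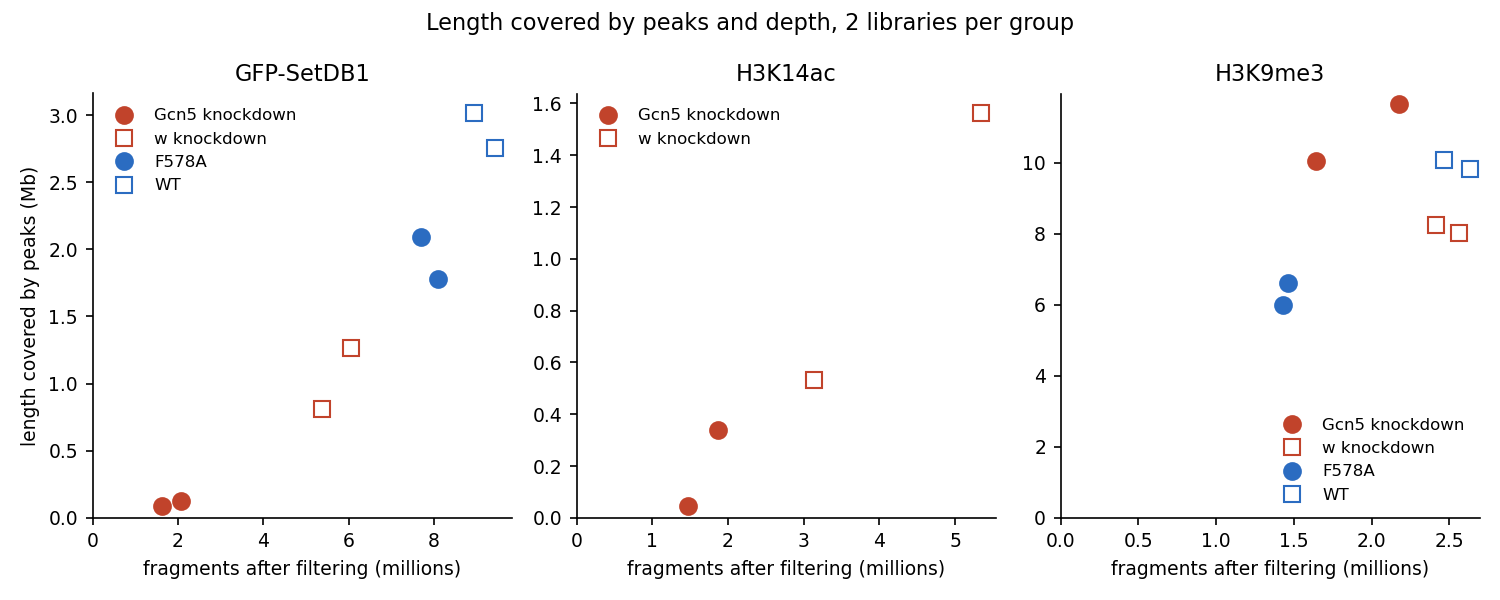
Length covered by peaks against depth for each library of the knockdown and F578A experiments, 2 per group. GFP-SetDB1 covered 0.091 and 0.126 Mb in the Gcn5 knockdown at 1.63 and 2.08 M fragments, and 0.813 and 1.26 Mb in the w knockdown at 5.37 and 6.05 M.

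In F578A embryos GFP-SetDB1 peaks were kept at a larger share of the WT regions in the chromosome arms than in heterochromatin. GFP-SetDB1 F578A libraries held 2493 and 2345 peaks and WT libraries 3216 and 2606 (log2 ratio -0.27), over 1.78 and 2.09 Mb against 3.02 and 2.75 Mb (log2 ratio -0.57), at 85.9% of the WT depth. The heterochromatin share was 20.3% and 33.4% in F578A and 38.0% and 41.0% in WT, a difference of -12.6 percentage points (exact permutation p = 0.333). With a library left out the difference ranged from -19.2 to -6.07 percentage points. With the same number of peaks per library the groups overlapped (19.3% and 33.4% against 33.2% and 42.0%). In the arms 69.6% of 1485 WT regions were kept and 11.5% lost, and in heterochromatin 29.0% of 544 were kept and 30.9% lost (16.9% and 50.6% with an overlap of at least 50% of the region). Kept regions had a median fold enrichment of 2.28 in heterochromatin and 3.25 in the arms. The kept shares of both compartments were not matched for this strength. The stage of the F578A and WT embryos used for ChIP-seq was not given in the sources used here.

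Over all 2200 WT regions, 56.7% (54.6 to 58.8) were kept and 18.2% (16.7 to 19.9) lost. WT replicates shared 67.4% and 82.3% of their peaks. Of the 5 strongest regions of WT alone, 4 lay on unplaced scaffolds and 1 at 3L:24442852-24443390 (fold enrichment 3.52). Among 90 regions found in F578A alone, the strongest overlapped Ack, a gene for a tyrosine kinase (3L:4108016-4108349, 3.75), the T-box gene org-1 (X:8452194-8452459, 3.39), Asap and the nuclear pore gene Nup50 (2R:8122847-8123174, 2.99), the 4612 bp at 3R:91281-95892 without a gene (2.95), and the thioredoxin gene Trx2 (2L:9612875-9613241, 2.76). On chromosome 4, GFP-SetDB1 covered 2.27% and 1.92% in F578A and 5.08% and 2.63% in WT.

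H3K9me3 peaks in F578A were about as many as in WT and covered less. There were 3347 and 3168 peaks against 3511 and 3469 (log2 ratio -0.10), over 6.6 and 5.99 Mb against 9.81 and 10.1 Mb (log2 ratio -0.66), with no overlap of groups (exact permutation p = 0.333) and 56.8% of the WT depth. The heterochromatin share was 77.8% and 79.6% against 74.9% and 76.8% (difference 2.8 percentage points), and turned to -3.23 with peaks of a −log10 q of at least 5. Of 3180 WT regions 65.8% (64.1 to 67.4) were kept and 19.4% (18.0 to 20.8) lost, with 63.2% of heterochromatin regions and 64.3% of arm regions kept. With an overlap of at least 50% of the region, 34.2% of all were lost, and 41.8% of heterochromatin regions and 34.8% of arm regions kept. Chromosome 4 was covered to 2.8% and 1.93% in F578A and to 4.31% and 4.12% in WT. The 5 strongest regions of either genotype alone all lay on unplaced scaffolds.

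In w1118 embryos H3K14ac peaks covered more of the genome at each later stage. They covered 2.91, 10.2 and 25.5 Mb at stages 4, 5 and 6 (a log2 ratio of 3.13 from stage 4 to 6), in 3096, 9603 and 10561 peaks. With a fold enrichment of at least 2 there were 2922, 2729 and 3008 peaks over 2.73, 3.45 and 9.49 Mb. Under this filter the number hardly grew and the length grew mainly from stage 5 to 6. With a −log10 q of at least 5 both grew at each stage, with 56, 803 and 2582 peaks over 0.0468, 1.08 and 7.95 Mb. H3K9me2 covered 9.12, 7.4 and 10.5 Mb and H3K9me3 5.73, 4.92 and 8.52 Mb. Each value is 1 library, so there is no test, and depth is not known. The heterochromatin share of H3K14ac was 4.77%, 2.6% and 2.82%, and that of H3K9me2 and H3K9me3 between 83.1% and 85.8%. On chromosome 4 H3K14ac covered 0.221%, 2.57% and 13.9%. H3K9me2 covered 3.48%, 2.83% and 3.71% of it in lists of another kind, which do not compare with these in length.

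The strongest H3K14ac peaks at stage 6 lay at Ref1, an mRNA export factor (3R:7079191-7080416, fold enrichment 5.17), borr, the gene for borealin of the chromosomal passenger complex (2L:9252464-9253096, 5.01), His3.3A with Nepl3 (2L:5055144-5055992, 4.64), Ts, the gene for thymidylate synthase (2L:2968940-2969643, 4.63), and DCTN3-p24, a dynactin subunit (2R:23062035-23062606, 4.51). All 5 had a peak at stage 5, and borr and Ts had none at stage 4. The strongest H3K9me2 and H3K9me3 peaks lay on unplaced scaffolds, on Y (Y:2720686-2721648, 7.65) and on a ribosomal RNA pseudogene of the X (X:23270911-23274860, 12.3). Of the stage 4 H3K14ac peaks 72.8% were found at stage 5 and 87.6% at stage 6.

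H3K14ac overlapped the H3K9 marks more than shifted peaks at stage 4 and less at stage 6, in the arms and in heterochromatin alike. At stage 5 the compartments parted. The shifts did not mask assembly gaps or unmappable sequence, which may lower the shifted shares. At stage 4, 6.36% of 3083 H3K14ac peaks met an H3K9me2 peak, against a median of 3.92% after shifting (highest of 1000 shifts 4.9), and 4.8% met an H3K9me3 peak (median 2.69, highest 3.73). At stage 5 the shares were 2.34% (median 2.63, shifts from 2.03 to 3.15) and 1.49% (median 1.78, from 1.39 to 2.16). In the arms they lay below every shift, at 0.957% for H3K9me2 (lowest 1.03) and 0.511% for H3K9me3 (lowest 0.707), and in heterochromatin above the median, at 35.1% (median 30.5, highest 37.7) and 24.8% (median 20.4, highest 26.9). At stage 6, 2.6% of 10547 peaks met H3K9me2 (median 4.54, lowest 3.8) and 2.47% met H3K9me3 (median 3.94, lowest 3.38). Peaks were shifted for the full lists only, so this pattern was not tested on stricter ones, where the H3K9me2 share at stage 4 was 14.3% with a −log10 q of at least 5 and 3.83% with a fold enrichment of at least 2.

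**Figure D4:**
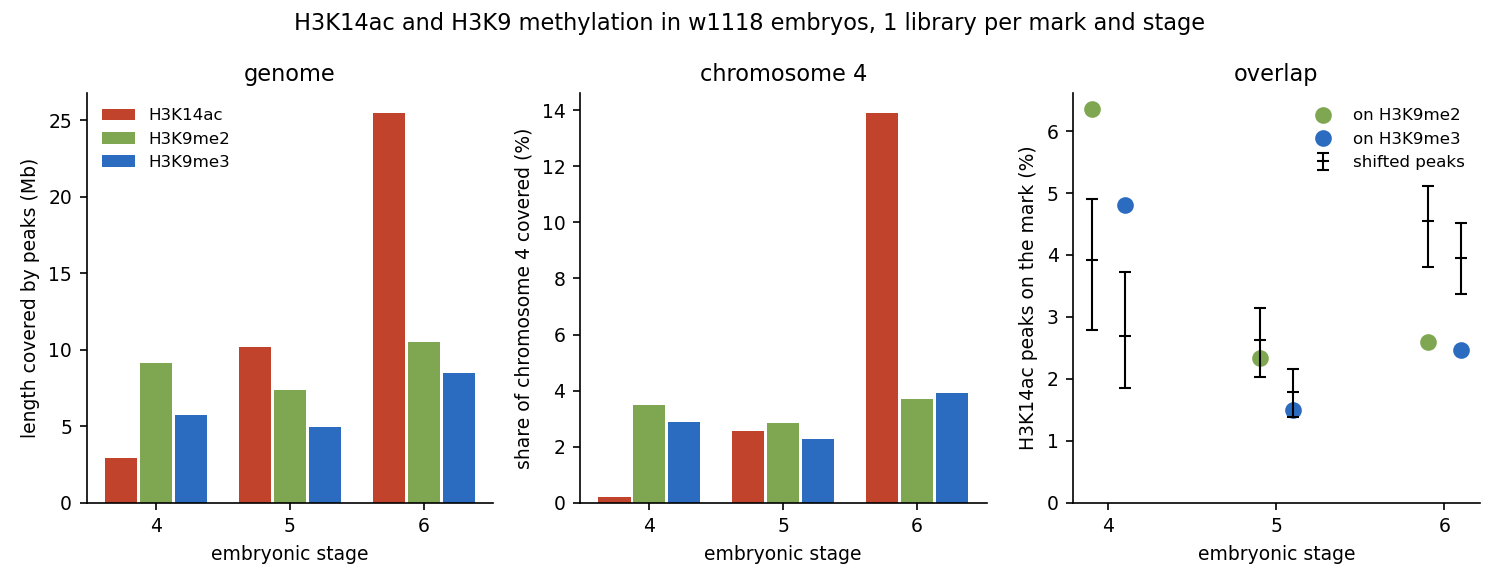
Length covered by peaks, share of chromosome 4 covered and overlap of H3K14ac with H3K9 methylation in w1118 embryos, 1 library per mark and stage. H3K14ac covered 2.91, 10.2 and 25.5 Mb at stages 4, 5 and 6, and black bars give the range of 1000 shifts (lengths do not compare between H3K14ac and the H3K9 marks).

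GFP-SetDB1 lay on H3K14ac and on H3K9me3 more often than shifted regions did. The shifts did not mask assembly gaps or unmappable sequence, which may lower the shifted shares. In WT embryos 23.7% of 2029 GFP-SetDB1 regions met an H3K9me3 region (median of shifts 10.4, none of 1000 as high), and 40.1% met a stage 5 H3K14ac peak of w1118 embryos (median 11, none as high). In the w knockdown 24.5% of 343 GFP-SetDB1 regions met H3K9me3 (median 14.6, 1 of 1000 shifts as high) and 3.5% met H3K14ac (median 0.292, 1 as high), with few H3K14ac regions to meet. Of the same regions 65.0% met a GFP-SetDB1 region of WT embryos (median 3.79). Of 636 H3K14ac regions of the w knockdown, 95.3% met a stage 5 peak of w1118 embryos (median 14.5). In heterochromatin of the w knockdown, 34.0% of 191 GFP-SetDB1 regions met H3K9me3 (median 25.1, 19 of 1000 shifts as high).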

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

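The tests in this part were chosen after the results were seen, except the test of older embryos, which was written before. Mariner2_DM was picked out because its log2 fold change differed between the Gcn5 knockdown and F578A, by 3.69 in a test of the difference itself. H3K9me3 was picked out because with all peaks every library moved up in the Gcn5 knockdown and down in F578A: the log2 ratios differed by 0.41 for the number of peaks and by 1.07 for the covered length, and these differences were not tested. With a −log10 q of at least 5 the opposition was gone. The log2 ratios were then -0.48 (Gcn5 knockdown) and -0.36 (F578A) for number, and -0.27 and -0.68 for length. With a fold enrichment of at least 2 the opposition stayed, at 0.33 and -0.07 for number, and 0.42 and -0.65 for length. The F578A libraries also had 56.8% of the WT depth. No group had 4 to 10 samples, so no sample was tested for standing apart.

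The longer H3K9me3 coverage in the Gcn5 knockdown could have come from deeper libraries, but the log2 ratio of depth was -0.38 with no overlap of groups, so higher depth is excluded. Older embryos in the knockdown are another candidate explanation. The gained length lay in stage 6 rather than stage 5 peaks 3.43 times as strongly as the control length, as predicted for older embryos. Yet length present in only 1 of a pair of same-stage libraries gave 2.64 to 2.69, so the threshold set in advance was too low and the test cannot tell. A −log10 q of at least 5 turned the length to a log2 ratio of -0.27, while a fold enrichment of at least 2 left it at 0.42. The gain thus depended on the filter, and why the filters parted was not tested.

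The counts of repeats were set against other groupings of the same libraries. In the Gcn5 comparison 1 of 10 splits, the real one, called as many repeats (2, highest other 0), and with the replicate block 1 of 4 splits that part every pair (73, highest other 0), too few splits for a share under 0.05. For lists the real count was 0, which 10 of 10 splits reach by construction, so this tests nothing, and the highest other was 11. In the F578A comparison 2 of 10 splits called as many repeats: the split that put F578A replicates 1 and 2 with WT replicate 1 called 348 against the real 1, which points to a structure of the samples that is not the genotype. For lists 2 of 10 splits gave at least the real 9, the highest being 12. The axis behind this held 83.9% of the variance within groups in the F578A experiment and 55.4% in the Gcn5 experiment. For the difference between effects, 14 of 100 splits called as many repeats (up to 136). Of these, 3 regrouped both experiments, and the others kept the real grouping of at least 1 experiment, so the count does not show what a random grouping gives. The correlation of effects was matched by 70 of 100 pairs of splits over all repeats (up to 0.556) and by 12 of 100 over transposable elements (up to 0.556), the real pair included. These pairs also hold splits that keep the real grouping of an experiment and splits that do not part same-numbered libraries. The counts therefore do not show what a random grouping gives either.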

How the results depend on the processing

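Of 1021 alternatives for 113 results, 829 were counted as unchanged, 31 as reversed, 36 as weaker, 82 as stronger and 43 as moved. Results with a threshold were unchanged if they kept direction and side of it. For ChIP-seq peak numbers, lengths and heterochromatin shares only the sign had to stay, whatever the size. Kept and lost shares had to stay within the Wilson interval of the value first reported. Where no construction is named, the cause was not tested. The Gcn5 count of 2 became 14 with DESeq2, 15 without a filter, 8 with transposable elements alone (fewer repeats tested), 73 with the replicate block, which removes spread shared by pairs, 8 with all 12 libraries, 26 with elements alone and the block, 21 with DESeq2 on elements alone, and 1 to 13 with a library left out. The F578A count of 1 became 29, 30, 10, 7, 3, 14 and 14 in the same order, and 1 to 3. The difference between effects, 1, became 6 with DESeq2, 8 without a filter, 2 with elements alone, 4 with the block, 13 with both, and 1 to 2. Lists in the Gcn5 comparison numbered 0 to 3 with a library left out; of the 9 in F578A, 1 stayed with an estimated correlation, 0 with fry, and 3 to 10 with a library left out. The correlation of effects was 0.371 over transposable elements.

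Signs turned for repeats near zero. In the Gcn5 comparison ROO_I-int gave -0.0283 with total counts and -0.13 to 0.22 with a library left out, SAR_DM -0.00981 and -0.33 to 0.34, DNAREP1_DM -0.34 to 0.0221 and PROTOP_B -0.33 to 0.00314. In F578A ROO_I-int gave -0.27 with elements alone, -0.26 with the block added, -0.31 with DESeq2 and -0.00355 to 0.0562 with a library left out. R2_DM gave 0.0427 with total counts, 0.0125 with a mean of at least 50 counts and -0.14 to 0.14 with a library left out. DNAREP1_DM gave -0.0426, -0.0408 and -0.0847 and PROTOP_B -0.00343 and -0.0418 in the fits of elements alone.

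For peaks, a −log10 q of at least 5 turned the GFP-SetDB1 share in the Gcn5 knockdown to 4.59 and the same number of peaks to 6.83. For H3K9me3 it turned number and length to -0.48 and -0.27 and the share to 0.945 (0.638 with the same number of peaks, -1.80 to 1.03 with a library left out). It turned the H3K9me3 share in F578A to -3.23. An overlap of at least 50%, stricter by construction, gave kept and lost shares of 6.7% and 83.4%, 2.47% and 85.4%, 75.3% and 12.6%, 49.5% and 26.0%, and 46.1% and 34.2%, in the order of the comparisons. From stage 4 to 6 the log2 ratio of H3K14ac length was 7.41 with a −log10 q of at least 5 and 1.80 with a fold enrichment of at least 2, where the share changed by -1.20. With these filters and the 50% overlap, H3K14ac met H3K9me2 at 14.3% and 3.83% (stage 4), 1.87%, 0.366% and 1.81% (stage 5), and 1.36%, 0.598% and 1.71% (stage 6), and H3K9me3 at 16.1%, 2.74% and 3.39%, at 0.44% and 1.07%, and at 1.51%, 1.2% and 1.31%. In all 5 ChIP-seq comparisons the treated libraries were shallower, which limits what lower peak numbers and lengths show.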

Other observations

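The tests in this part were chosen after the results were seen, except the test of loss at H3K14ac-marked chromatin, which was written before. In the edgeR fits of all repeats without a block, no repeat was called in both comparisons, which had only 2 and 1 calls. With the replicate block, which the F578A libraries do not call for, ROVER-I_DM and (ATCTAC)n were up in both, against 0.052 expected if calls were independent, and (CCGGCT)n was down in both, against 0.052. In the fits of transposable elements alone BURDOCK_LTR was up in both, against 0.192 expected. These expected numbers take every repeat as equally likely to be called, so they do not show that the effects are shared. The main axis of variation within groups had similar loadings in both experiments, with a correlation of 0.519 over 1410 repeats and of 0.697 over 103 transposable elements.

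Fewer GFP-SetDB1 and H3K14ac peaks in the Gcn5 knockdown could come from lower sequencing depth or from the knockdown. In 4 of 4 groups of 2 libraries of these antibodies and knockdowns the deeper library had more peaks, which depth predicts. Of the other 6 groups the deeper library had more peaks in 4, and fewer in GFP-SetDB1 of WT (2606 against 3216) and H3K9me3 of the w knockdown (3984 against 4138). The number of knockdown libraries at least as deep as a control library of the same antibody was 0, so the data cannot tell an effect of the knockdown from depth.

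The lower heterochromatin share of GFP-SetDB1 in F578A may also have technical sources. Lower sequencing depth would lower the share in the shallower library of each pair, and this was seen in 1 of 4 groups, which cannot tell. With the same number of peaks per library the difference was -11.3 percentage points, close to the -12.6 with all peaks, although F578A replicate 2 then overlapped WT, so the number of peaks cannot be excluded by the rule written for it.

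As a hypothesis, F578A might lose SetDB1 at H3K14ac-marked chromatin. In the arms, 12.3% of 171 lost WT regions met a stage 5 H3K14ac peak against 60.1% of 1033 kept regions. Within strata of fold enrichment the difference was -35.8 percentage points (two-sided permutation p = 0.0001, the smallest 10000 permutations can give). This is opposite to what the hypothesis predicts for regions that lost their peak altogether. Peaks were scored as present or absent, so weaker binding at kept regions could not be seen. Regions rather than libraries were permuted, and the H3K14ac peaks came from w1118 embryos. Kept regions in the arms were also wider (median 514 against 420 bp), and width was not matched. Lost regions were weaker than kept ones, with a median fold enrichment of 2.00 against 3.25, and in the arms 11.7% of them met H3K9me3 against 2.32% (5.91 percentage points within strata, permutation p = 0.0367) and 20.5% met H3K9me2 against 4.07% (permutation p = 0.069). In heterochromatin 7.74% of lost and 23.4% of kept regions met H3K14ac (permutation p = 0.167 within strata), and 31.0% and 34.2% met H3K9me3 (permutation p = 1).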
